A study of Caenorhabditis elegans with 4 samples.

How the data were processed

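RNA of wild-type Caenorhabditis elegans at the L3 stage, the third of the larval stages between hatching and the adult, was hybridised to 2-colour DNA microarrays. Each of 4 arrays carried 1 numbered L3 preparation in the second channel and a wild-type mixed reference RNA in the first channel, per the labels. What the reference was mixed from is not given in the sources used here, nor whether the 4 preparations came from separate cultures. The limma p-values of single genes therefore measure only the spread between these preparations, which may be technical. There is 1 group of 4 samples and no other group, so the only comparison the design allows is that of L3 with the reference, tested as a mean log2 ratio different from 0. This test leaves out the spread of the reference itself. Since the reference was in the first channel on every array, a channel or dye bias of a probe that repeats on every array cannot be separated from a difference between the RNAs.

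The deposited values are log2 ratios of the 2 channels, 1 per probe and array. The authors' background correction, normalization, spot filter and scanner settings are not given in the sources used here, and spot intensities were not analysed here, so signal over background is unknown and the number of arrays limits the precision. When 2 was raised to the power of each value, between 99.96% and 100.0% of the results on an array were multiples of 0.001 (within 0.02 of a step). This held for 5.1% to 5.4% of the inverse ratios, so the values are log2 of a ratio rounded to 0.001 in this orientation. The lowest ratios therefore carry rounding error. The dyes are not labelled. The direction L3 over reference is called likely, because the descriptions name L3 before the reference and the reference is channel 1. The rounding does not tell which channel was divided by which. The deposited column medians were 0.02, 0.00, -0.03 and -0.01 for preparations 1 to 4, so the arrays had been centred near 0, by a method that stays unknown.

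The table holds 21632 probes. An annotation table paired 16450 of them with 1 gene symbol and 247 with several, and 4935 are unnamed here. Symbols were updated through Entrez gene numbers to the names of RefSeq assembly WBcel235 for 16360 probes, and 90 kept the annotated symbol. The genome build of the probes is not given in the sources used here, so no coordinates are reported and the reference served for names and chromosomes only. The probes of a gene were averaged per array, which joined probes for 1448 of 14958 named genes; probes with no name or several were kept apart under their number and given no gene name. A value was present for 21400, 21058, 21214 and 21472 probes on arrays 1 to 4.

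Each array was centred on its median, and genes or probes with a value on at least 3 of the 4 arrays were tested, 19943 in all (14936 named genes and 5007 other probes). The tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. In simulated data on these 19943 genes, with 50 genes changed at each size, the fit called 0% of 1.5-fold changes, 20% of 2-fold, 70% of 4-fold and 82% of 8-fold changes, and 4 of 19743 unchanged genes. Only 200 genes were changed there, while 3806 passed in the real data. The adjustment was therefore stricter in the simulation, and these shares are not the sensitivity of the real fit.

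Before the data were examined, 39 gene lists were fixed, together with the tests, the alternatives and the rule for genes named in the text. That rule took the 10 highest and 10 lowest mean ratios among genes past the threshold with 1 sign on 4 arrays, up to 3 passing members of each list with the largest mean (or the single largest where none passed), the vitellogenins vit-2, vit-5 and vit-6, rme-2, the msp genes, lin-14, lin-28, lin-29, col-19, unc-54 and glp-1 where measured, and the 5 genes with the largest SD. No probe carried the names lin-14 or lin-28 here, and these genes are not analysed here. A gene named outside this rule is said to have been chosen after its values were seen. The lists share 22 of their 1824 genes. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. The shift of each of 38 lists with 5 or more measured genes was tested against all other genes with the camera statistic, written out for the intercept of this model on z scores of limma's moderated statistic with a preset correlation of 0.01 between genes, and adjusted over the lists. It was repeated with a correlation estimated for each list, where only 3 degrees of freedom remain, and with fry, which asks whether the genes of a list move on balance 1 way and compares them with no other genes. In 200 random lists of simulated data the preset test gave 3 unadjusted p-values under the threshold. The simulated genes were independent of each other, so this does not show how the preset test behaves on correlated genes. In the real lists the estimated correlation ran from 0 (cytochrome P450 genes) to 0.643 (major sperm proteins). The preset test sets the z scores of a list against their spread over genes, not over the 4 preparations. Its p-values can therefore be far too small for lists whose genes are correlated by more than 0.01. The camera test was also run by chromosome. The spread of a list is the median over its members of the SD over the 4 arrays, set as a percentile against 10000 random lists of the same size matched on the mean ratio.

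The alternatives were values as deposited without centring, arrays scaled to a common median absolute deviation, quantile normalization, a value on all 4 arrays or on at least 2, probes kept apart, robust eBayes, and each replicate left out in turn. The array names give 3 print series of slides, with preparations 1 and 2 in 1 series, and 2 array months, preparations 1 and 2 against 3 and 4. Fits with the array month as a random block, and on the arrays of each month alone, were added after the data were seen. Flags for single preparations, list correlations and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.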

Results

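The data describe which transcripts of wild-type C. elegans differ between the L3 larval stage and a mixed reference RNA. Log2 ratios, likely L3 over reference, were measured in 4 L3 preparations, 1 array each. Values are given as mean ± SD over the 4 preparations, n = 4 unless stated, and positive values mean more transcript in L3. The arrays were of similar orientation, with Pearson correlations across probes between 0.620 and 0.723 for the 6 pairs of arrays; probes are not independent replicates. The median absolute deviation of the deposited log2 ratios was 0.38, 0.58, 0.39 and 0.28 on arrays 1 to 4.

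The genes with the lowest ratios included those of egg yolk proteins, and those with the highest ratios included infection-response and detoxification genes. The yolk protein genes vit-5 and vit-2 lay at -6.32 ± 0.93 and -5.78 ± 0.76, which are 79.7-fold and 54.9-fold lower in L3. ule-3, named for expression in the uterus, lay at -5.98 ± 0.91, and the uncharacterised ZK813.3, ZK813.1 and D1054.10 at -6.06 ± 1.02, -5.80 ± 1.00 and -5.67 ± 1.08. At the other end stood irg-5 at 6.38 ± 1.5 (83.3-fold higher in L3), irg-4 at 5.28 ± 1.58 and irg-8 at 4.02 ± 0.54, members of a group named for induction by infection. Also among the 10 highest were the UDP-glucuronosyltransferase genes ugt-8 (4.63 ± 1.12) and ugt-22 (3.91 ± 0.89), whose enzymes conjugate small molecules to sugars, and pud-2.1 (4.39 ± 0.93) and pud-4 (3.86 ± 1.75). Every gene named so far in this paragraph had 1 sign on 4 of 4 arrays and passed the threshold, because the rule that chose them required both. Their limma adjusted p-values lay between 0.000377 and 0.00871. Among probes with no gene name here, 2777823 (5.69 ± 1.14) and 2786645 (5.21 ± 0.97) were highest, and 2777825 (-6.15 ± 0.90) and 2803445 (-6.03 ± 0.93) lowest.

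**Figure D1:**
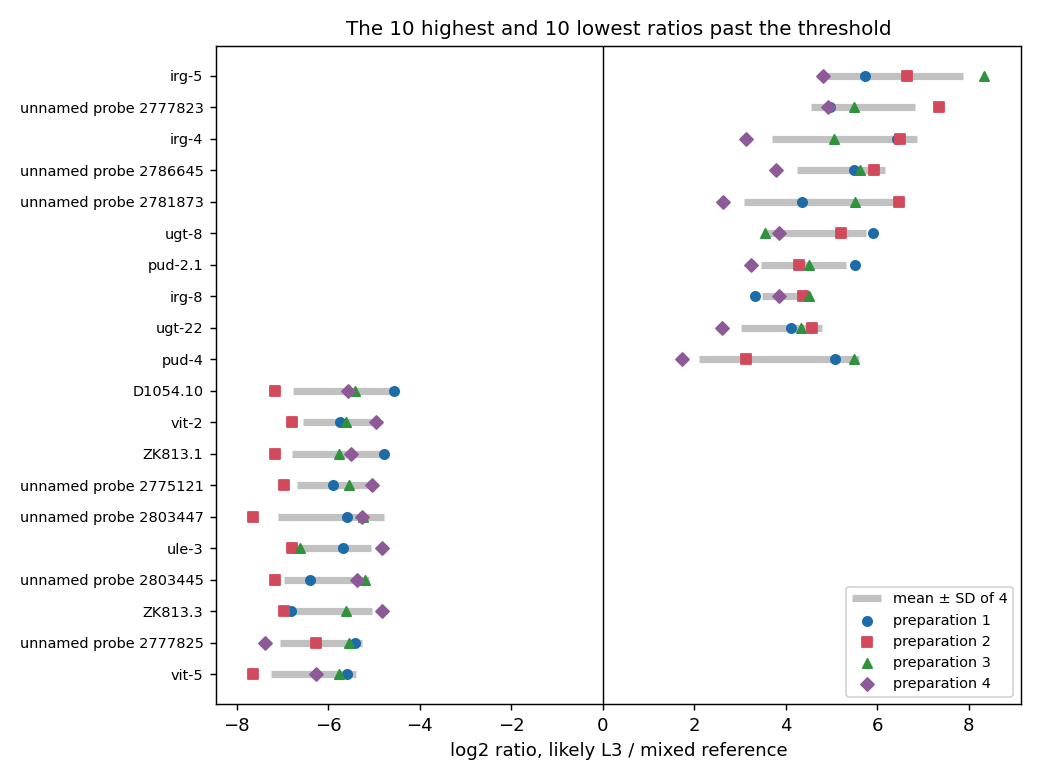
Log2 ratio, likely L3 over mixed reference, of the 10 highest and 10 lowest genes or unnamed probes past the threshold; coloured points are the 4 preparations and grey bars the mean ± SD. The means run from 6.38 for irg-5 to -6.32 for vit-5, and all 4 preparations of each gene lie on 1 side of 0, as the rule for choosing them required.

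In all, 3806 of 19943 genes and probes passed the threshold in limma, 1657 higher and 2149 lower in L3, of which 920 and 1277 differed at least 2-fold. A total of 7004 had an unadjusted p under 0.05. Of 19201 measured on all 4 arrays, 8868 (46.2%) had 1 sign on every array. With 1 preparation left out, and so fewer arrays in the fit, 1893 (without preparation 1), 2573 (without 2), 1938 (without 3) and 2732 (without 4) genes passed, of which 793, 1047, 925 and 1092 were higher and 1100, 1526, 1013 and 1640 lower.

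Transcripts of oocytes, eggshell and yolk were lower in L3 throughout. All 23 measured oocyte and eggshell genes passed the threshold on the low side, and 23 did when adjusted over the list alone, with a list median of -3.39 and preparation medians between -3.72 and -3.20. pos-1, which encodes a maternal RNA-binding protein, lay at -4.96 ± 0.46, the eggshell gene perm-2 at -4.83 ± 0.20 and cpg-2, a chondroitin proteoglycan of the eggshell, at -4.72 ± 0.27. The yolk receptor gene rme-2 lay at -3.68 ± 0.57. All 3 vitellogenin genes measured were lower, both over all genes and adjusted over the list alone, vit-6 at -5.03 ± 0.84; this list was too small for the list test. The oocyte list was shifted against all other genes (camera adjusted p = 5.7e-25, preset correlation), and adjusted p = 0.434 with an estimated correlation.

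Part of the germ line, meiosis and cell cycle transcripts were also lower, by less. Of 42 DNA replication and cell cycle genes 23 were lower and 0 higher (27 lower adjusted over the list alone; median -1.02), with the B-type cyclin genes cyb-3 at -2.45 ± 0.43 and cyb-1 at -1.83 ± 0.42 and the ribonucleotide reductase gene rnr-2 at -1.92 ± 0.63. Of 26 meiosis genes 17 were lower and 1 higher (17 and 1 adjusted over the list alone; median -0.79), among them zim-1 (-1.27 ± 0.15), zim-2 (-1.24 ± 0.17) and dsb-1 (-1.18 ± 0.07), which act in chromosome pairing and in making meiotic breaks. The higher one was cra-1, at 0.92, named outside the rule after its values were seen. Of 20 germ line proliferation and P granule genes 8 were lower (10 lower and 1 higher adjusted over the list alone; median -0.54), including the translational regulator gene gld-1 (-2.31 ± 0.62), cgh-1 (-2.05 ± 0.68) and gld-3 (-1.40 ± 0.56). glp-1, the germ line Notch receptor gene, lay at -0.55 ± 0.18 (limma adjusted p = 0.0493), and this call was lost without any 1 of the preparations (adjusted p from 0.0761 to 0.163), with a value on at least 2 arrays (0.05002) and at probe level (0.0516). The list test gave adjusted p = 1.6e-11 for the cell cycle, 2.6e-08 for meiosis and 0.0021 for the germ line list, and adjusted p = 0.434, 0.434 and 0.523 with an estimated correlation. In fry the germ line list was lost (adjusted p = 0.0993). Without preparations 1, 2, 3 and 4 in turn, 6, 16, 10 and 11 meiosis genes and 3, 6, 3 and 6 germ line genes were lower.

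Most major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, were lower in L3, to a depth that differed between preparations. Of 30 measured, 25 were lower and 0 higher (28 lower adjusted over the list alone), with a list median of -1.53, and msp-65 (-2.34 ± 1.51), msp-113 (-2.23 ± 1.00) and msp-57 (-2.14 ± 0.85) had the lowest means. The 5 that did not pass were msp-32 (-0.78), msp-38 (-0.13), msp-59 (-1.47), msp-63 (-0.70) and msp-78 (-2.02). The list medians were -0.67, -1.53, -1.34 and -2.86 in preparations 1 to 4. The list was shifted (camera adjusted p = 5.6e-12, and adjusted p = 0.434 with an estimated correlation). The count of lower genes depended on the setting: 12 when arrays were scaled to a common spread, 21 with quantile normalization, and 19, 11, 10 and 24 without preparations 1, 2, 3 and 4. In the remaining settings it was 24 to 27, and 28 of 33 at probe level. With the array month as a block, whose correlation was negative (-0.117) and so lowered standard errors, msp-32 and msp-78 passed (adjusted p = 0.0420 and 0.0471). Without preparation 4, msp-32, msp-63 and msp-78 passed (adjusted p = 0.0313, 0.0496 and 0.0333, with means of -1.03, -1.12 and -1.19). The call of msp-65 was lost without 1, 2 or 3 (adjusted p = 0.0565, 0.0549 and 0.0718) and with scaled arrays (0.0711). These genes are nearly identical in sequence and probes may hybridise to several of them, so single members are uncertain. The 2 probes of msp-59 lay at -1.91 and 1.26 in preparation 2. The 54 other sperm genes had a median of -0.10 (-0.161 without preparation 3 and -0.045 without 4). Of these, 9 were lower and 0 higher (9 and 0 adjusted over the list alone). Their list was not shifted (camera adjusted p = 0.229), except in preparations 3 and 4 alone (list median -0.12, adjusted p = 0.0214). The lowest of them were ssp-37 (-1.77 ± 0.60), sss-1 (-1.58 ± 0.92, lost without preparation 2 or 4, adjusted p = 0.0722 and 0.0694) and ssq-2 (-0.99 ± 0.25). Leaving out preparations 1, 2, 3 and 4 in turn left 5, 4, 3 and 2 sperm genes lower, with 1 higher in the last.

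**Figure D2:**
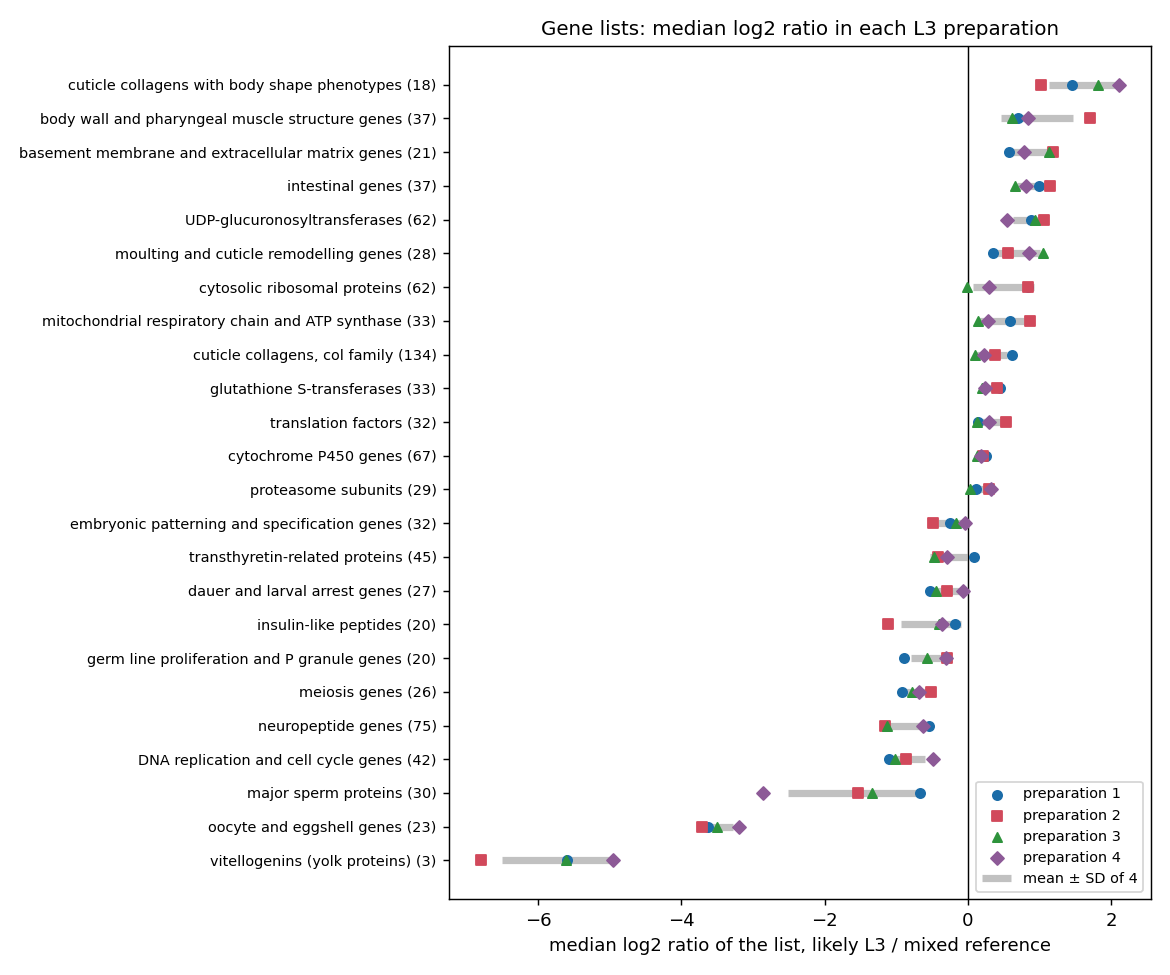
Median log2 ratio, likely L3 over mixed reference, of the 22 gene lists shifted in the camera test with preset correlation, of the vitellogenins (3 genes, too few for the test) and of the col family (not past the threshold); coloured points are the 4 preparations, grey bars the mean ± SD of the 4 medians, and numbers in brackets the genes measured. The list medians of preparations 1 to 4 spread from -0.67 to -2.86 for the major sperm proteins and from -3.72 to -3.20 for oocyte and eggshell genes.

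Cuticle genes moved in both directions. In the col family, which encodes collagens of the cuticle, 39 genes were higher, 31 lower and 64 did not pass (53 higher and 36 lower adjusted over the list alone). The list as a whole was not shifted (median 0.36, camera adjusted p = 0.164), except without preparation 3 (adjusted p = 0.0174) and in preparations 1 and 2 alone (0.0098). The largest changes were downward, in col-36 (-4.87 ± 0.41), col-158 (-4.41 ± 0.33) and col-45 (-4.33 ± 0.86), and col-19, a collagen gene of the adult cuticle, lay at -3.54 ± 0.81. Without preparation 1, 21 col genes were higher. Of 18 collagen genes with body shape phenotypes 13 were higher and 1 lower (16 and 1 adjusted over the list alone; median 1.67), with dpy-5 at 2.78 ± 0.89 and lon-3 at 2.76 ± 0.68 against dpy-17 at -3.17 ± 0.70. Among 28 moulting and cuticle remodelling genes 10 were higher and 0 lower (15 and 0 adjusted over the list alone; median 0.80), led by qua-1 (1.91 ± 0.63), the metalloprotease gene nas-36 (1.87 ± 0.81) and noah-2 (1.70 ± 0.60). Counts of 7, 6, 6 and 5 moulting genes were higher without preparations 1 to 4 in turn. Body shape collagens were shifted with camera adjusted p = 1.4e-06 and moulting genes with 1.5e-05, and adjusted p = 0.434 for both with an estimated correlation. The 68 hedgehog-related and patched-related genes held 15 higher and 10 lower (23 and 11 adjusted over the list alone), with grl-20 at -3.32 ± 0.62, grl-17 at -2.86 ± 0.68 and grd-14 at 2.62 ± 1.33, the last lost without preparation 1 (adjusted p = 0.0543). Their list test missed the threshold (median 0.33, adjusted p = 0.0653) except without preparation 3 (0.0235), and 5, 11, 7 and 4 were higher without preparations 1 to 4. Collagen genes are similar in sequence, and their probes may cross-hybridise.

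Part of the muscle and extracellular matrix genes were higher in L3. Of 37 genes of body wall and pharyngeal muscle structure 17 were higher and 0 lower (24 and 0 adjusted over the list alone; median 0.87), led by dim-1 (2.18 ± 0.22), unc-52, which encodes perlecan (1.94 ± 0.65), and the troponin gene tnt-2 (1.82 ± 0.31). The myosin heavy chain gene unc-54 lay at 1.71 ± 0.34. Of 21 basement membrane and matrix genes 10 were higher and 0 lower (12 and 1 adjusted over the list alone; median 0.75), with the laminin gene epi-1 at 2.14 ± 0.36 and the nidogen gene nid-1 at 1.68 ± 0.43; unc-52 is in both lists. Muscle genes were shifted with camera adjusted p = 3.2e-09 and matrix genes with 3.2e-06, and adjusted p = 0.434 for both with an estimated correlation. Without preparation 3, 11 muscle and 6 matrix genes were higher.

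Many intestinal and UDP-glucuronosyltransferase genes were higher as well, while cytochrome P450 and glutathione S-transferase genes moved in both directions. Of 37 intestinal genes 20 were higher and 3 lower (23 and 6 adjusted over the list alone; median 0.93), led by acdh-1 (3.72 ± 1.07), an acyl-CoA dehydrogenase gene, the P-glycoprotein gene pgp-1 (3.37 ± 1.34) and the protease gene cpr-5 (3.11 ± 0.66). Of 62 UDP-glucuronosyltransferase genes 32 were higher and 1, ugt-18 (-2.47, named after its values were seen), was lower (43 and 3 adjusted over the list alone; median 0.91). ugt-13 lay at 4.42 ± 2.13 (n = 3, lost without preparation 3, adjusted p = 0.0765). Cytochrome P450 genes numbered 14 higher and 6 lower of 67 (14 and 8 adjusted over the list alone; median 0.27), with cyp-35A5 at 3.62 ± 1.61, cyp-35A3 at 3.62 ± 2.43 and cyp-35A2 at 2.52 ± 0.47. The call of cyp-35A3 was lost without preparation 1 or 3 (adjusted p = 0.0994 and 0.0924). Without preparations 1 and 3 in turn, 8 and 9 P450 genes were higher and 2 and 2 lower. Of 33 glutathione S-transferase genes 9 were higher and 4 lower (15 and 4 adjusted over the list alone; median 0.42), among them gst-38 (2.40 ± 0.90), gst-13 (2.02 ± 0.25) and gst-3 (-1.98 ± 0.49). Camera gave adjusted p = 1.3e-05 for intestinal genes, 1.0e-11 for UDP-glucuronosyltransferases, 0.0262 for cytochrome P450 and 0.0452 for glutathione S-transferase genes, the last lost without preparation 1 (adjusted p = 0.114). In preparations 3 and 4 alone the P450 and glutathione S-transferase lists were lost (adjusted p = 0.0625 and 0.106). For each of the 4 lists adjusted p = 0.434 with an estimated correlation. Without preparation 2 or 3, 2 glutathione S-transferase genes were lower. The lipid synthesis and beta-oxidation list split, with 14 higher and 7 lower of 32 (17 and 9 adjusted over the list alone; median 0.58, camera adjusted p = 0.0864, 0.0457 without preparation 3, and 0.0411 in preparations 1 and 2 alone). Without preparation 1 or 3, 9 lipid genes were higher. In this list acdh-1 was highest and the acyl-CoA synthetase gene acs-2 (-3.81 ± 0.57) and the fatty acid desaturase gene fat-3 (-2.91 ± 0.13) lowest.

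As lists, genes of protein synthesis and respiration lay slightly above 0, and few single members passed. The 62 cytosolic ribosomal protein genes had a median of 0.49 with 6 higher and 0 lower (0 and 0 adjusted over the list alone), and preparation medians of 0.85, 0.85, -0.02 and 0.30. The highest, rpl-11.2 (0.84 ± 0.38), rpl-37.1 (0.74 ± 0.44) and rps-15 (0.73 ± 0.39), were each lost without at least 1 preparation. For rpl-11.2 this held without 1, 2 or 4 (adjusted p = 0.101, 0.0661 and 0.0765), and for rpl-37.1 and rps-15 without any 1 (adjusted p from 0.0768 to 0.140 and from 0.0530 to 0.149). rpl-37.1 was also lost with values as deposited, with a value on at least 2 arrays and at probe level (adjusted p = 0.0533, 0.0505 and 0.0508). Of 33 respiratory chain and ATP synthase genes 8 were higher and 0 lower (14 and 2 adjusted over the list alone; median 0.49, and 0.29 without preparation 2; preparation medians 0.59, 0.86, 0.14 and 0.28), with ucr-2.2 at 1.60 ± 0.58, gas-1 at 0.83 ± 0.16 (lost without preparation 1 or 4, adjusted p = 0.0624 and 0.0505) and ucr-1 at 0.77 ± 0.35 (lost without any 1, adjusted p from 0.0656 to 0.0909). Of 32 translation factor genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.34). inf-1 lay at 1.17 ± 0.33, and the cap-binding protein genes ife-2 and ife-3 moved apart, at 1.22 ± 0.25 and -1.49 ± 0.11. None of 29 proteasome genes passed in limma (0 higher and 0 lower, 0 adjusted over the list alone), with a median of 0.18 (0.28 and 0.12 without preparations 3 and 4) and pas-6 the highest at 0.46 ± 0.43. Camera gave adjusted p = 3.4e-07 for ribosomal, 1.3e-04 for respiratory, 0.0305 for translation factor and 0.0446 for proteasome genes, and adjusted p = 0.523, 0.523, 0.523 and 0.624 with an estimated correlation. All 4 lists were lost in fry (adjusted p = 0.119, 0.0948, 0.0502 and 0.131) and in preparations 3 and 4 alone (0.0870, 0.0781, 0.0717 and 0.0627), and the proteasome list in preparations 1 and 2 alone (0.213). Without preparation 2 or 4 the translation factor (adjusted p = 0.0565 and 0.0556) and proteasome (adjusted p = 0.0707 and 0.243) lists were lost. Without preparations 1, 2, 3 and 4, 0, 0, 1 and 0 ribosomal and 1, 2, 3 and 1 respiratory genes were higher, and 3 translation factor genes without preparation 3 or 4.

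Many neuropeptide genes were lower in L3. Of 75 measured 43 were lower and 2 higher (51 and 4 adjusted over the list alone; median -0.84), the lowest being nlp-32 (-2.35 ± 0.38), nlp-28 (-2.19 ± 0.98) and nlp-55 (-2.03 ± 0.79). Without preparations 2 and 3, 25 and 17 were lower. Some nlp genes, nlp-28 among them, encode antimicrobial peptides of the epidermis and not transmitters. Of 20 insulin-like peptide genes 7 were lower and 3 higher (9 and 3 adjusted over the list alone; median -0.55), with ins-17 at -1.64 ± 0.33, ins-11 at -1.19 ± 0.52 (lost without preparation 3, adjusted p = 0.0636, and at probe level, 0.0874) and ins-3 at -1.14 ± 0.37. The 2 probes of ins-11 lay at 0.12 and -1.65 in preparation 4. Without preparation 1 or 3, 3 insulin genes were lower. Camera gave adjusted p = 1.3e-11 for neuropeptides and 0.0146 for insulins, and adjusted p = 0.434 and 0.523 with an estimated correlation. In fry the insulin list was lost (adjusted p = 0.0627). Of 51 other synaptic and neuronal genes 8 were lower and 3 higher (8 and 3 adjusted over the list alone). Their list median was -0.22, and -0.145 and -0.317 without preparations 2 and 4. The list test gave camera adjusted p = 0.0545, 0.0137 without preparation 4, and 0.0165 in preparations 1 and 2 alone. Counts of 0, 4, 0 and 8 of these genes were lower without preparations 1 to 4. ida-1 and egl-3, genes of dense core vesicles and peptide processing, lay at -1.03 ± 0.37 and -0.98 ± 0.33 (both lost without preparation 1 or 3, adjusted p from 0.0543 to 0.0675). cat-2, at 1.04 ± 0.61, was lost without any 1 (adjusted p from 0.0550 to 0.125).

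Genes of dauer larvae and of embryos were lower in part. Of 27 dauer and larval arrest genes 9 were lower and 3 higher (11 and 4 adjusted over the list alone; median -0.17, and -0.32 without preparation 4), with hsp-12.6 at -4.26 ± 0.95, the cuticlin gene cut-1 at -4.17 ± 0.66 and dod-3 at -3.78 ± 0.67. Of 32 embryonic patterning genes 5 were lower and 0 higher (4 and 0 adjusted over the list alone; median -0.27, and -0.15 and -0.14 without preparations 1 and 2), among them the homeodomain gene pal-1 (-1.99 ± 0.42), the Wnt gene mom-2 (-1.95 ± 0.27) and sdz-28 (-1.14 ± 0.35). Without preparation 1, 2 or 3, 3 were lower. Of 45 transthyretin-related genes 10 were lower and 1 higher (12 and 2 adjusted over the list alone; median -0.21, and -0.39 without preparation 1). ttr-2 lay at -1.84 ± 0.26, while ttr-50 (-3.11 ± 1.97) and ttr-51 (-1.82 ± 1.11) were near 0 in preparation 4 and lost without 1, 2 or 3 (adjusted p from 0.0727 to 0.109). Camera gave adjusted p = 0.0189 for dauer, 0.0329 for embryonic and 0.0048 for transthyretin-related genes, the embryonic list being lost without preparation 1 (0.0510) and in preparations 3 and 4 alone (0.0870). The transthyretin-related list was lost in fry (adjusted p = 0.0960) and in preparations 1 and 2 alone (0.0554). With an estimated correlation these were adjusted p = 0.434, 0.434 and 0.523. Among 12 heterochronic genes, which time larval fates, lin-41 (-1.61 ± 0.52) and hbl-1 (-1.16 ± 0.57) were lower and dre-1 higher (0.92 ± 0.60). Adjusted over the list alone 3 were higher and 2 lower, with no list shift (median -0.07, camera adjusted p = 0.894). hbl-1 was lost without 1, 2 or 3 (adjusted p from 0.0592 to 0.0821) and dre-1 without 2, 3 or 4 (0.0792 to 0.142) and with scaled or quantile-normalized arrays (0.0739 and 0.0606). lin-29, needed for the larval-to-adult switch, lay at 0.70 ± 0.42 (limma adjusted p = 0.0547, and 0.0474 with scaled arrays, 0.0419 with quantile-normalized arrays and 0.0408 with the array month as a block).

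The other lists did not pass the camera test on the median-centred ratios of all 4 preparations. C-type lectins held 22 higher and 16 lower of 202 (22 and 16 adjusted over the list alone; median 0.14, camera adjusted p = 0.157), the lowest being clec-87 (-4.61 ± 0.19), clec-91 (-4.19 ± 0.60) and clec-88 (-3.72 ± 0.43). Without preparation 1 or 3, 13 lectin genes were higher. Lysozyme and antimicrobial peptide genes held 8 higher and 14 lower of 53 (10 and 18 adjusted over the list alone; median -0.15, and -0.31 without preparation 1), with the caenacin gene cnc-2 at -3.87 ± 0.88 and the thaumatin-like thn-2 and thn-1 at -3.52 ± 0.57 and -3.26 ± 0.46. Their camera adjusted p was 0.0546. It was 0.0289 and 0.0349 without preparations 1 and 2, 0.0442 with scaled and 0.0375 with quantile-normalized arrays, and 0.0081 in preparations 3 and 4 alone. In the other settings it lay between 0.0560 and 0.434, and fry gave 0.0237. Totals of 4, 5, 3 and 3 genes were higher without preparations 1 to 4. Heat shock protein genes held 6 higher and 4 lower of 21 (10 and 4 adjusted over the list alone; median 0.48, adjusted p = 0.169, and 0.0163 in fry), among them hsp-12.3 (-3.63 ± 0.41) and the chaperone gene hsp-3 (1.95 ± 0.37). Nuclear hormone receptors held 18 higher and 12 lower of 239 (6 and 6 adjusted over the list alone; median 0.04, adjusted p = 0.50), with nhr-73 at 2.31 ± 0.46, nhr-259 at 2.14 ± 0.99 and nhr-21 at -2.3 ± 0.39 (n = 3). Counts of 6, 6, 7 and 10 were higher without preparations 1 to 4. Histones held 4 higher and 6 lower of 62 (4 and 5 adjusted over the list alone; median -0.12, adjusted p = 0.169), the lowest being the linker histone-like genes hil-7 (-2.38 ± 0.87), hil-3 (-2.15 ± 0.76) and hil-4 (-1.41 ± 0.79, lost without 1, 3 or 4, adjusted p from 0.0665 to 0.0878). Counts of 2, 7, 2 and 3 were lower without preparations 1 to 4. Vulva and somatic gonad genes held 6 lower of 38 (2 lower adjusted over the list alone; median -0.14, adjusted p = 0.200), with sqv-1 (-1.03 ± 0.23) and sqv-8 (-0.92 ± 0.27, lost without preparation 3, adjusted p = 0.0573), which act in glycosaminoglycan synthesis. lip-1 also passed (-0.68 ± 0.32, lost without any 1, adjusted p from 0.0540 to 0.152). Counts of 2, 2, 1 and 3 were lower without preparations 1 to 4.

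Innexin genes held 3 higher and 5 lower of 20 (5 and 6 adjusted over the list alone), including inx-8 (-2.22 ± 0.28) and inx-14 (-1.66 ± 0.38), gap junction genes of the gonad, and inx-3 (-1.47 ± 0.19). The list median was 0.05, its mean -0.17 and its camera adjusted p 0.591, so median and mean differ in sign. Of 16 tubulin genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone). Their list median was 0.21 (camera adjusted p = 0.301), and 0.10 without preparation 2. tba-4 lay at 2.21 ± 0.22, tbg-1, the gamma-tubulin gene, at -0.74 ± 0.22 (lost without 1, 3 or 4, adjusted p from 0.0621 to 0.0887) and mec-12 at 0.65 ± 0.25 (lost without any 1, adjusted p from 0.0561 to 0.138). Of 17 male-enriched genes only cwp-4 passed (-0.56 ± 0.16; 0 adjusted over the list alone; list median 0.07, adjusted p = 0.859), and of 24 RNA-processing and splicing genes only prp-38 (-0.65 ± 0.26; 0 adjusted over the list alone; list median 0.02, adjusted p = 0.812). cwp-4 was lost without any 1 preparation (adjusted p from 0.0965 to 0.124) and prp-38 without 1, 2 or 3 (adjusted p from 0.0898 to 0.137).

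Of the 38 lists tested, 22 were shifted with the preset correlation, 12 higher and 10 lower, and 0 with an estimated correlation (adjusted p between 0.434 and 0.624 for those 22). The genes of the X chromosome, on which few germ line genes lie, had a median 0.073 above that of the autosomes, at 0.078 ± 0.039 over the 4 preparations. Of 2225 X genes 287 were higher and 199 lower. Against the other chromosomes this shift did not pass (camera adjusted p = 0.339); fry, which asks only whether X genes moved on balance 1 way, gave adjusted p = 0.0355.

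The preparations differed from each other most, relative to matched random lists, in the msp genes, the col family and the hedgehog-related genes. Against matched random lists, the SD over preparations was above the 95th percentile for the msp genes (median SD 0.88, percentile 100), the col family (0.69, 100), hedgehog-related genes (0.59, 99.96), moulting genes (0.61, 98.9), ribosomal protein genes (0.47, 97) and heterochronic genes (0.51, 96.0). By percentile it was lowest for proteasome (0.21, percentile 0.020), oocyte and eggshell (0.31, 0.10) and meiosis genes (0.30, 1.06). Only the col family stayed above the 95th percentile with each preparation left out. Without preparation 4 the percentile was 53.2 for msp, 36 for hedgehog-related and 90.7 for heterochronic genes. Without preparation 3 it was 20.1 for ribosomal and 89.9 for hedgehog-related genes, and without preparation 1 it was 70.4 for moulting and 72.4 for heterochronic genes. With scaled arrays the oocyte list moved to percentile 99.7 and the meiosis list to 31.9, and with quantile normalization they moved to 22.45 and 49.1. Heterochronic genes lay at percentile 94.4 with values as deposited. The largest SDs of single genes were those of EGAP798.1 (3.41) and mag-1 (3.38).

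**Figure D3:**
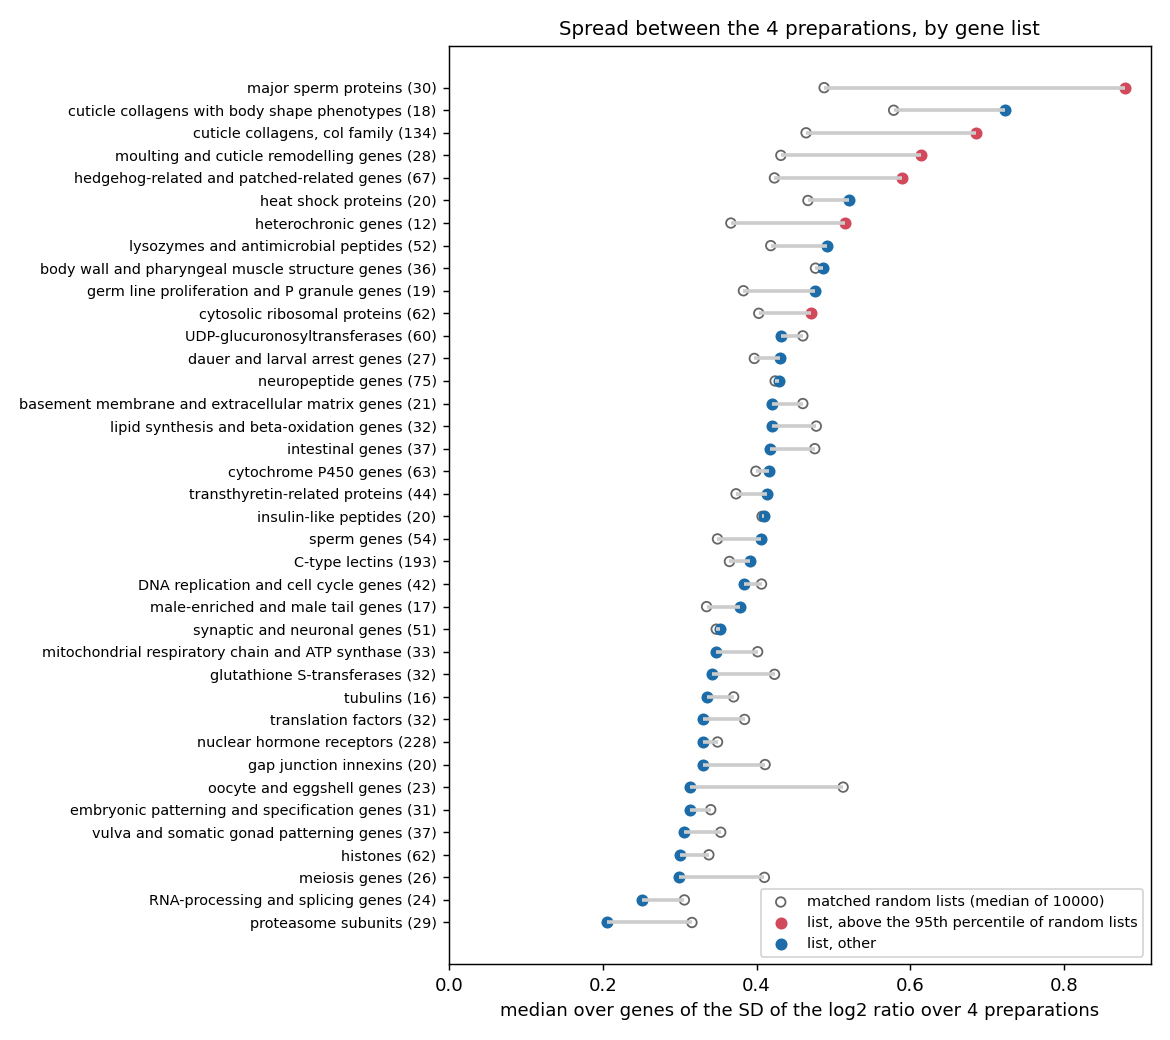
Median SD of the log2 ratio over the 4 preparations for each gene list (filled points; red above the 95th percentile of matched random lists, blue otherwise) and the median of 10000 matched random lists (open circles); numbers in brackets are genes with 4 values. The median SD is 0.88 for major sperm proteins and 0.21 for proteasome subunits.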

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

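For each named gene, and for the list values, the preparation farthest from the others was compared with the range of all 4 by Dixon's ratio at the 95% level. Of 198 values tested 8 stood apart, where chance gives about 1 in 20, or 9.9. Preparation 2 stood apart in 4 of them. EGAP798.1 was at 6.65 in preparation 2 and between -0.46 and 0.07 in the others. The perlecan gene unc-52 was at 2.90 in preparation 2 against 1.55 to 1.69. The sperm gene ssp-37 was at -2.67 in preparation 2 against -1.51 to -1.43, and the unnamed probe 2803447 at -7.65 against -5.60 to -5.24. In preparation 3, nhr-73 was at 3.00 against 2.04 to 2.14, and lin-29 at 1.32 against 0.43 to 0.57. In preparation 4, prp-38 was at -0.26 against -0.82 to -0.74, and ttr-51 at -0.18 against -2.60 to -2.25.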

How the results depend on the processing

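The fits on the arrays of 1 month and with the array month as a block were chosen after the data were seen. A random block for the print series was planned but could not be fitted here with 3 series on 4 arrays. The array month as a block (correlation -0.117) gave 4489 genes, with all 3806 of the main fit among them. A negative correlation lowers the standard error of the mean in this model. The added calls, such as msp-32, msp-78 and lin-29, are therefore no sign that allowing for a batch strengthened them. No paired analysis was possible because there is only 1 group. With another centring, scale, normalization, filter, probe level or eBayes, 3761 to 4480 genes passed. Leaving out 1 preparation gave 1893 to 2732 genes, 793 to 1092 higher and 1013 to 1640 lower; preparations 1 and 2 alone gave 1527 (703 higher, and 824 lower, all 824 at least 2-fold) and preparations 3 and 4 alone 1713 (726 and 987), from fewer arrays. Of 149 named genes that passed, 109 passed in every leave-one-out fit. Lists shifted numbered 22, 17 to 25 in other settings, and 0 with an estimated correlation, which keeps 3 degrees of freedom. The mean moderated statistic of X genes in fry was 0.452. Lists with a wide spread rose from 6 to 11 with scaled and 10 with quantile-normalized arrays; the cause was not tested.

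No shifted list or passing named gene changed sign; those that did had not passed: male-enriched genes at probe level (-0.0046), heterochronic genes without 1 preparation (-0.15 to 0.14) and in preparations 3 and 4 (0.20), splicing genes (-0.021 to 0.091, and -0.017 in 3 and 4), innexins (-0.062 to 0.13, -0.082 in 1 and 2, and -1.15 as fry's mean statistic, adjusted p = 0.0390), the col family in fry (-0.474), and, with 1 preparation left out, EGAP798.1 (-0.14 to 2.23), probe 2799671 (-2.24 to 0.34) and probe 2804787 (-0.073 to 2.34); the cause was not tested. Signal over background was not given, so no filter on it was tried.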

Other observations

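Gene classes outside the fixed lists were taken from symbol prefixes with at least 15 measured genes, 101 in all, after the data were seen. Of 16 skr genes, which encode Skp-related proteins of ubiquitin ligases, 10 were lower in L3 and 0 higher (median -1.14), with skr-9 at -2.98 ± 0.60 and skr-8 at -2.96 ± 0.99. Of 23 pals genes 8 were lower (median -0.53), led by pals-26 (-2.36 ± 0.93) and pals-39 (-2.09 ± 0.52), and of 41 nssp genes 13 were lower (median -0.36). Of 17 vha genes, which encode subunits of the vacuolar proton pump, 10 were higher and 1 lower (median 0.88); vha-6 lay at 1.75 ± 0.45 and vha-12 at 1.52 ± 0.34, and the lower one was vha-18 at -1.67 ± 0.44. Mitochondrial ribosomal protein genes were higher in part, 9 of 20 mrps genes (1 lower, mrps-11 at -1.33 ± 0.36) and 6 of 25 mrpl genes with mrpl-12 at 1.45 ± 0.18. Of 18 sec genes of the secretory pathway 6 were higher, among them sec-61.A (1.28 ± 0.35). Camera adjusted p-values over the 101 classes were 2.6e-05 for skr, 6.5e-04 for pals, 8.2e-04 for nssp, 2.6e-04 for vha, 0.0015 for mrps, 0.0030 for mrpl and 0.0025 for sec, and adjusted p = 0.622 for each with an estimated correlation (0.624 for nssp). These classes are a selection, and others passed too. The 43 math genes, with 9 higher and 2 lower, had camera adjusted p = 0.0029, and 0.622 with an estimated correlation.

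In the 3 patterns that follow, the tests of array scale, sperm RNA, array month and sign patterns were chosen after the results were seen; those of dim spots and of shared deviations were set before their results were seen. When the signs of whole arrays were turned, the 8 distinct patterns gave 3806 genes for the real one and at most 0 for any other, so 1 pattern of 8 gave as many; 8 patterns are too few for a share under 0.05.

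The depth of the major sperm protein decrease ranged over 2.18 between the list medians of the 4 preparations and was greatest in preparation 4. The range was 3.32 after scaling to a common spread. Array 4 had the smallest median absolute deviation (0.28), so this scaling was bound to deepen its median and cannot decide whether array scale played a part. The oocyte and eggshell medians, -3.63 in preparation 1 and -3.20 in preparation 4, argue against a scale common to all genes as the whole cause. Array month as the whole cause is excluded, because the major sperm protein medians differed within a month. They differed by 1.52 between preparations 3 and 4 and by 0.86 between 1 and 2. Whether an equal change of all sperm RNA, in the L3 preparation or in its reference, was the whole cause could not be decided. The median of preparation 1 minus preparation 4 was 1.98 for major sperm protein genes (quartiles 1.45 and 2.45) and 0.371 for the 54 other sperm genes (SD 0.676), and 0.371 plus 1 SD is 1.05. After scaling, the medians were 3.17 and 0.557. For the 9 other sperm genes called lower the unscaled median was 0.472 (SD 0.562). Another 45 did not pass and signal over background is unknown, so the other sperm genes may not follow the amount of sperm RNA. The 0.371 was above all matched random lists (random median -0.037). Those lists hold unrelated genes, while the sperm genes deviated together (mean correlation 0.195, against 0.0442 at the 95th percentile of random lists). Preparations 1 and 4 were also the extremes of the major sperm protein medians. Sperm RNA may be a part of the difference, but this comparison cannot show it. Whether it was, how large that part is, what made any rest, and whether the larvae differed in age, stays open.

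The col family varied between preparations more than matched random lists. Its spread stayed at percentile 100 after the arrays were scaled. That scaling also moved the oocyte list from percentile 0.1 to 99.7, so it cannot exclude a different scale of the arrays. The members deviated together (mean correlation 0.0963, against 0.0412 at the 95th percentile of random lists). Noise of single spots thus did not make all of the deviations, but so small a correlation leaves open how much of the spread it made. Proteasome genes, whose spread was lowest, had a larger mean correlation (0.378), so shared deviation does not by itself explain a wide spread. The hedgehog-related genes also stayed at percentile 100 after scaling, with the same limit. Their correlation of 0.0791 lies at percentile 98.1, between the bounds set beforehand, so noise and shared change cannot be told apart. Their wide spread rested on preparations 3 and 4. A difference in age within the moulting cycle is a candidate explanation that was not tested.

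Chemoreceptor genes, a class noticed in the data, lay slightly above 0. Of 1112 measured, 73.9% had a mean above 0, against 51.6% of all genes, with a median of 0.20 and preparation medians of 0.22, 0.20, 0.20 and 0.05, while 27 were higher and 9 lower in limma. The class was not tested as a whole. Among its families, srx, str and srh passed over the 101 classes (camera adjusted p = 0.0024, 0.0027 and 0.0040, and 0.622 for each with an estimated correlation). So did srg, srw, srd, srt and srz (camera adjusted p = 0.0208, 0.0216, 0.0225, 0.0248 and 0.0286, and 0.622 to 0.624 with an estimated correlation). Others did not pass, among them sri, srj, sre and srb (camera adjusted p = 0.381, 0.305, 0.517 and 0.906). Many chemoreceptor genes could give dim spots, whose ratios might be biased. A probe was taken as dim where its array 2 ratio was 0.793, the commonest there, times a quotient of whole numbers up to 3. Without spot intensities this mark could not be checked. Such ratios were more common among chemoreceptor probes (2.23%) than among others (1.06%, Fisher's exact test, two-sided p = 0.000826). Yet on arrays 1, 3 and 4 such dim probes of other genes had a median of 0.0014 (bootstrap interval -0.046 to 0.038), below the 0.19 of chemoreceptor probes. The dim probes were chosen by their array 2 ratios around 0.793, below 1, which may by itself lower their median on other arrays. Of the 236 dim probes, about 58.2 would be expected by accident, from counts at neighbouring ratios. The test thus cannot exclude a bias of dim spots, and no biological explanation was tested.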
